A study of Homo sapiens with 12 samples.

How the data were processed

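RNA-seq was carried out on 12 libraries of HCT116 p53-/- cells, a human colorectal carcinoma line in which both copies of the p53 gene are disrupted. The libraries fall into 4 groups of 3 replicates per the labels: the parental cells, called wild-type here; a clone with a CRISPR/Cas9 deletion in ORC2; a clonally selected line in which ORC2 with its untranslated regions was expressed again from a vector, called the rescue; and a CRISPR/Cas9 clone with a deletion in ORC5. ORC2 and ORC5 encode subunits of the origin recognition complex, which marks replication origins and loads the MCM helicase. Each altered genotype is represented by 1 clone. The labels state poly(A) selection, a directional kit and paired-end reads on HiSeq2000 or NextSeq instruments, without saying which library ran on which instrument. They do not state whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

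The deposited table holds counts per gene symbol, made by the authors with no normalization, as whole numbers that sum to 48561547 to 78633654 per library. Per the submitters' processing notes the tools were FastQC 0.11.5, HISAT2 2.2.1, SAMtools 1.12, HTSeq 2.0.5 and DESeq2 1.42.0 on genome build hg38. Gene annotation, strand setting and read filters are not stated. Symbols of paralogs with near-identical transcripts can share reads in such counts. The authors also deposited a list of genes higher and a list of genes lower after ORC2 deletion, as symbols without values, and with no threshold stated. Of 54651 symbols in the count table, 50928 were matched to the RefSeq annotation of GRCh38 by symbol and 640 by synonym, and 3083 were not matched. Transcript length and GC content from GENCODE were available for 37191 symbols.

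Genes with enough counts were kept with filterByExpr by group, which left 18846 genes holding 99.952% to 99.966% of each library's counts. Libraries were scaled by TMM factors, and all 12 were fitted together with a term per group in edgeR 4.0.16 under R 4.3.3 (quasi-likelihood F test, robust, 8 residual degrees of freedom). The 5 comparisons tested were ORC2 deletion, ORC2 rescue and ORC5 deletion against wild-type, ORC2 rescue against ORC2 deletion, and ORC2 deletion against ORC5 deletion. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and a second count also required a log2 fold change of at least 1 in size. Levels are TMM-scaled CPM values, given as mean ± SD with n = 3, and log2 fold changes are given ± SE. For named genes with at most 30 counts in a group, the ratio of summed counts, divided by the summed TMM-scaled library sizes, is given with a 95% binomial interval (Clopper-Pearson). Such intervals cover counting error only.

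Gene lists were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Lists with at least 5 tested members entered the test, which were 27 of 31 lists. The lists were origin licensing, origin firing and replication fork, mitosis, DNA repair, p53 targets, interferon response, NF-kB and inflammatory, developmental transcription factors, HOX clusters, clustered protocadherins, zinc finger ZNF genes, Polycomb machinery, heterochromatin and DNA methylation, cohesin, condensin and CTCF, cancer-testis and germline, imprinted genes, intestinal epithelium, epithelial adhesion, mesenchymal and EMT, WNT targets, cholesterol synthesis, integrated stress response, hypoxia and glycolysis, NRF2 targets, ribosomal proteins, mitochondrially encoded transcripts, replication-dependent histones, and markers of fibroblasts, blood cells, endothelial cells and neural cells. Chromosomes were tested as sets with camera and an estimated correlation, and median changes were taken over windows of 10 Mb holding at least 15 genes with a mean CPM of at least 5.

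Comparisons, tests, lists and the rule for naming genes were set before the data were examined, and the 10 Mb windows were added later. The rule admits the ORC, CDC6, CDT1 and MCM genes; the 8 largest called changes each way per comparison (5 each way in rescue against wild-type and in ORC2 deletion against ORC5 deletion) among genes with a mean CPM of at least 5 in either group and no overlap between groups; up to 4 called members per list with a mean CPM of at least 1, or up to 2 highly expressed members where none was called; 10 genes that moved back in the rescue; and 10 genes changed the same way and 5 changed in opposite ways in both deletions. Part of the genes that it admits are named.

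Comparisons that share libraries are correlated by construction, so overlaps were set against 20 simulations of unchanged groups and against the overlap of independent gene sets. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a fit of only the groups compared, the replicate number as a block, glmTreat against 1.5-fold, fry and an estimated correlation for lists, and leaving out each library in turn. A fit without replicate 2 of both the ORC2 deletion and the rescue, sample quality weights in limma-voom, an offset for GC content and transcript length, the lists and overlaps without ORC2 deletion 2, and the licensing list without ORC2 were added after the data were seen. Residuals of ORC2 deletion and rescue libraries correlated by 0.154, 0.466 and 0.307 at the same number 1, 2 and 3. Across numbers, deletion 1 with rescue 3 gave 0.276 and deletion 3 with rescue 1 gave 0.172, while each pairing of number 2 with another number was negative (-0.401 to -0.199). By the criterion that each same-numbered pair exceeds 0.1, the numbers pair the ORC2 deletion with the rescue, but the data show mainly a deviation shared by the replicate 2 libraries, and numbers 1 and 3 are not told apart. Same-numbered libraries of other groups correlated by -0.169 to 0.111, and the replicate number entered as a block in an alternative fit.

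Recovery was tested on simulated data with 200 changed genes. With the spread of all 12 libraries, 1.5% of genes changed 1.5-fold, 43.3% of genes changed 2-fold and 80.3% of genes changed 4-fold were called in the ORC2 deletion, and 4.5%, 43.3% and 83.3% in the ORC5 deletion. With the spread of the 11 libraries other than ORC2 deletion 2, these shares were 68.7%, 82.1% and 92.4% in the ORC2 deletion and 47.8%, 71.6% and 89.4% in the ORC5 deletion. The simulations gave each library the same spread and changed 200 genes, while 4581 genes were called in the real ORC2 deletion. More changed genes ease the adjusted threshold, so these shares do not give the recovery of that comparison.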

Results

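Gene expression was measured by poly(A) RNA-seq in 12 libraries of HCT116 p53-/- cells, with 3 libraries each of wild-type cells, an ORC2 deletion clone, an ORC2 rescue line and an ORC5 deletion clone. The series asks which epigenetic and chromosome structure changes depend on ORC2. Total counts were 48561547, 54669564 and 60473469 in wild-type replicates 1 to 3 and 62704815, 50678957 and 62054434 in the ORC2 deletion. They were 78633654, 60230790 and 61610995 in the rescue and 74816892, 64397053 and 48629701 in the ORC5 deletion. The first principal component of the 18846 genes tested held 40.97% of the variance and the next held 19.26%.

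ORC2 deletion replicate 2 stood apart from the other libraries. Its genes deviated from the other replicates of its group by a median of 0.692 on the log2 scale, against 0.362 and 0.38 for replicates 1 and 3 and 0.086 to 0.256 in the other groups. Its difference from the other libraries followed GC content across genes (Spearman correlation 0.526, where genes are not independent replicates) and transcript length (-0.388). Ribosomal protein genes held 9.911% of its counts and mitochondrial genes 8.458%, against 5.295% and 6.437% in ORC2 deletion 1. Rescue replicate 2 showed a smaller deviation and also followed GC content (0.342). Wild-type 1 to 3 (-0.303, -0.344 and -0.376) were set against libraries that include ORC2 deletion 2, so no separate trend is shown. The biological coefficient of variation over the 12 libraries was 20.4%, and 8.7% without ORC2 deletion 2, and this shared spread enters the test of each comparison.

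**Figure D1:**
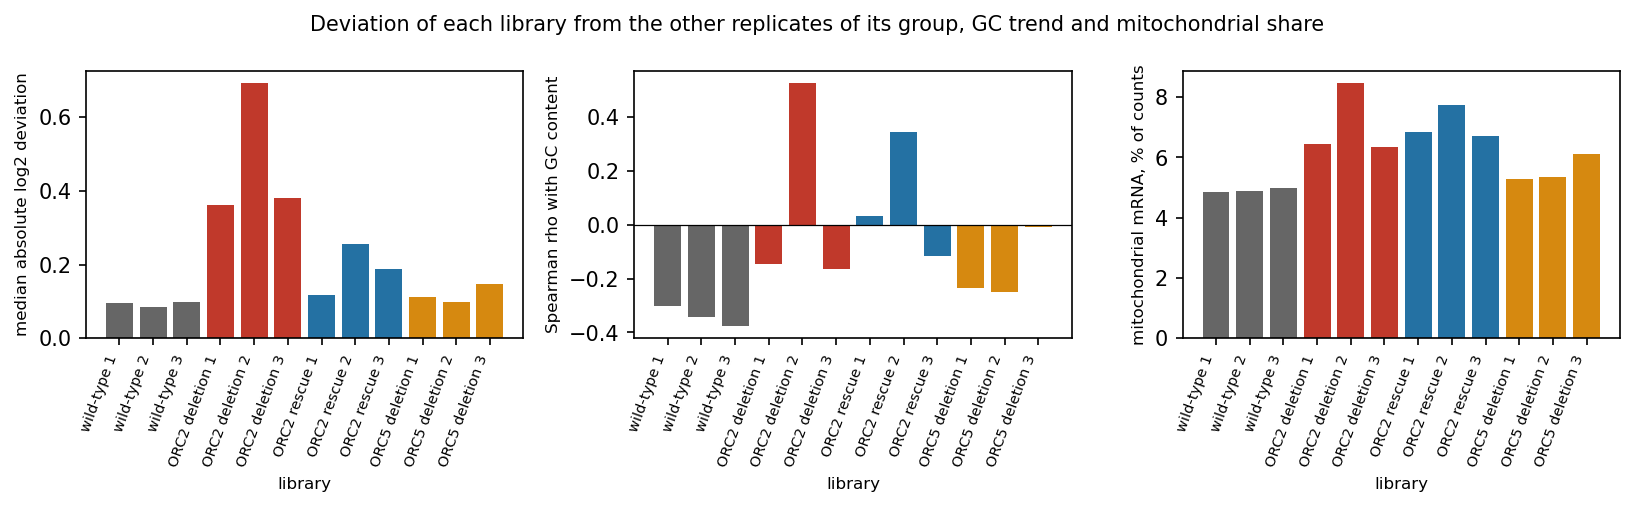
Median deviation from the other replicates, rank correlation with GC content and mitochondrial share of counts for the 12 libraries, each bar 1 library. ORC2 deletion 2 lies apart, with a median deviation of 0.692 from the other replicates of its group.

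ORC2, on chromosome 2 (200908977 to 200963660 of GRCh38), and ORC5, on chromosome 7 (104126341 to 104208013), are the genes targeted. ORC2 stood at 71.89, 73.77 and 74.36 CPM in wild-type replicates 1 to 3 and at 43.04, 31.24 and 43.1 CPM in the ORC2 deletion. It stood at 606, 523.6 and 638.9 CPM in the rescue and at 72.76, 70.63 and 71.63 CPM in the ORC5 deletion. ORC5 stood at 50.16, 46.39 and 45.55 CPM in wild-type cells and at 44.29, 35.88 and 42.42 CPM in the ORC2 deletion. It stood at 43.72, 44.98 and 43.61 CPM in the rescue and at 35.16, 36.06 and 34.85 CPM in the ORC5 deletion. Gene-level counts do not show whether the transcripts left in a deletion clone encode a full protein.

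**Figure D2:**
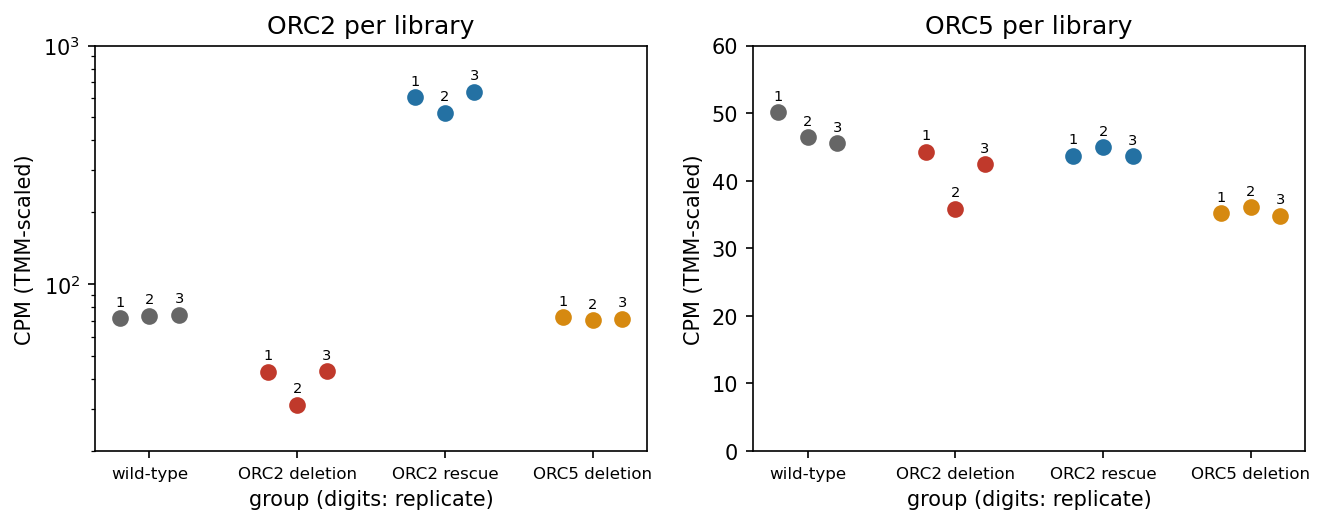
CPM of ORC2 and ORC5 in each library (points, 3 per group), on a log axis for ORC2. ORC2 lies at 31.24 to 43.1 CPM in the ORC2 deletion and at 523.6 to 638.9 CPM in the rescue.

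ORC2 deletion against wild-type asks which genes differ when ORC2 is deleted. By camera, the origin licensing and replication fork lists were lower and the mesenchymal and interferon response lists higher, with 5 of 17, 12 of 36, 9 of 15 and 11 of 20 genes called that way. These 4 list calls were lost with an estimated correlation (adjusted p = 0.19, 0.19, 0.137 and 0.19). ORC2 itself was 1.87-fold lower (log2 fold change -0.91 ± 0.13, adjusted p = 0.000548, and 0.0516 by glmTreat against 1.5-fold, the highest of the alternatives). CCN2, a secreted matrix-associated protein, was 14.7-fold higher at 71.7 ± 16.1 against 4.87 ± 0.376 CPM. RNF43, a ubiquitin ligase that removes WNT receptors, was 58.3-fold lower at 1.16 ± 0.328 against 66.9 ± 0.522 CPM. By edgeR, 2747 genes were higher and 1834 lower, of which 1426 and 589 changed at least 2-fold. These counts were 3706 and 3212 without ORC2 deletion 2, and without wild-type 1, 2 or 3 they were 1712, 1697 and 1677 higher and 1119, 1102 and 1085 lower. Of the 4581 genes, 4386 were also called in the same direction without ORC2 deletion 2, 4552 by DESeq2 and 1522 in a fit of the compared groups alone, which called 990 higher and 534 lower (755 and 342 at least 2-fold). Each genotype is 1 clone, so differences between clones that do not depend on the targeted gene enter each comparison.

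Among the largest increases at a mean CPM of at least 5 in either group, ALPP, an alkaline phosphatase whose paralogs can share its reads, had 3 counts over the wild-type libraries and 3474 in the ORC2 deletion, a ratio of 1130 (95% counting interval 387 to 5490). ALPK2, an alpha kinase, rose to 29.2 ± 4.58 CPM (log2 fold change 8.72 ± 0.38), and DCLK1, a doublecortin-like kinase, to 18.9 ± 5.22 CPM (8.54 ± 0.35). RARB, a retinoic acid receptor, rose by 7.71 ± 0.7, ANKRD1, an ankyrin repeat protein of muscle, by 7.32 ± 0.39, AK5, an adenylate kinase, by 6.45 ± 0.63, and ANO2, a chloride channel, by 6.45 ± 0.32 on the log2 scale. Count ratios with 95% counting intervals were 446 (249 to 894) for ALPK2, 403 (204 to 935) for DCLK1, 233 (99.5 to 719) for RARB, 163 (95.4 to 308) for ANKRD1 and 90.2 (52.5 to 170) for ANO2, from 5 to 13 counts in wild-type cells. KRT81, a hair keratin that can share reads with KRT86, rose by 6.41 ± 0.45 on the log2 scale and was 5.68 without ORC2 deletion 2. Among the largest decreases at that level, PDE4B, a cAMP phosphodiesterase, fell by 7.19 ± 0.3 on the log2 scale, from 131 ± 3.36 to 0.924 ± 0.494 CPM. ONECUT3, a homeobox transcription factor, stood at -7 ± 0.28, and PCDH7, a protocadherin, at -6.93 ± 0.18. YBX1, a nucleic acid binding protein on chromosome 1 (42682418 to 42703805), fell from 1220 ± 14.4 to 22 ± 0.85 CPM. ADGRF1, an adhesion G protein-coupled receptor, stood at -5.3 ± 0.37, FAM111B, a protease, at -5.06 ± 0.25, and MAL2, a protein of apical transport, at -5.01 ± 0.17. The adjusted p of these genes ranged from 2.19e-10 (YBX1) to 3.7e-05 (AK5).

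In the origin licensing list, 5 of 17 genes fell, and 7 when adjusted over the list alone, with a median log2 fold change of -0.22 (camera adjusted p = 0.0041, and adjusted p = 0.19 with an estimated correlation). ORC1, a subunit of the origin recognition complex, stood at -0.6 ± 0.09 (adjusted p = 0.000874). GMNN, the licensing inhibitor geminin, stood at -0.93 ± 0.09 and lies in a stretch of chromosome 6 from 1 to 30000000 whose genes were lower together in this clone. MCM2, a subunit of the replicative helicase, stood at -0.77 ± 0.23 (adjusted p = 0.0334), and at -0.48 without ORC2 deletion 2. Its call was lost without wild-type 1, 2 or 3 (0.083, 0.0862 and 0.0883), rescue 1 (0.0514) or ORC5 deletion 1, 2 or 3 (0.0504, 0.051 and 0.0574), and in a fit of the compared groups alone (0.18), within a range of 6.4e-09 to 0.443 over the alternatives. With ORC2 taken out of the list, its 16 genes gave a single camera p = 0.00294 (p = 0.0296 with an estimated correlation), a test added after the data were seen. GMNN, in the shifted stretch of chromosome 6, was still among them. In the origin firing and replication fork list, 12 of 36 genes fell, and 13 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.000285, and adjusted p = 0.19 with an estimated correlation). The licensing list had 11 genes lower and 1 higher without ORC2 deletion 2, and the fork list 24 and 2. RFC5, a clamp loader subunit, stood at -0.81 ± 0.16 and PRIM1, the primase, at -0.7 ± 0.13, and both calls were lost in a fit of the compared groups alone (adjusted p = 0.0781 and 0.0623, in ranges of 2.94e-10 to 0.229 and 7.46e-09 to 0.383).

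In the DNA repair list, 6 of 25 genes fell and 2 rose, the same numbers adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.00163, and adjusted p = 0.484 with an estimated correlation). With an offset for GC content and length its adjusted p was 0.13 (range 0.00039 to 0.13), and its median was -0.17 without ORC2 deletion 2, with 9 genes lower. FANCA, a Fanconi anemia repair protein, stood at -0.63 ± 0.09. In the cohesin, condensin and CTCF list, 4 of 19 genes fell, and 5 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.00124, and adjusted p = 0.484 with an estimated correlation). Its median was -0.22 without ORC2 deletion 2, with 8 genes lower. PDS5B, a regulator of cohesin, stood at -1.54 ± 0.2. In the Polycomb machinery list, 8 of 28 genes fell and 3 rose, 9 and 3 adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.0199, and adjusted p = 0.484 with an estimated correlation). PHC2, a subunit of a Polycomb complex, stood at -0.74 ± 0.12. The Polycomb call was lost without ORC2 deletion 2 (adjusted p = 0.124, median -0.19) and with the GC and length offset (0.0652), in a range of 0.00838 to 0.124. In the heterochromatin and DNA methylation list, 6 of 31 genes fell and 1 rose, 6 and 0 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0336, and adjusted p = 0.484 with an estimated correlation). EHMT1, a histone H3 lysine methyltransferase, stood at -0.6 ± 0.1. That list's call was lost without wild-type 3 (adjusted p = 0.0522), without ORC2 deletion 2 (0.0675, median -0.12) and with the GC and length offset (0.132), in a range of 0.0225 to 0.132.

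In the mesenchymal and EMT list, 9 of 15 genes rose and 2 fell, also adjusted over the list alone, with a median of 1.68 (camera adjusted p = 0.000285, and adjusted p = 0.137 with an estimated correlation). TGFBI, an extracellular matrix protein, rose by 5.74 ± 0.59 from 6 counts over the wild-type libraries, a count ratio of 54.1 (24.6 to 148). SNAI2, a transcription factor of epithelial to mesenchymal transition, stood at 4.25 ± 0.69 (count ratio 19.9, 11.2 to 39.1), and SPARC, a matrix-associated glycoprotein, at 3.62 ± 0.45. In the epithelial adhesion list, 6 of 22 genes rose and 5 fell, 6 and 6 adjusted over the list alone, and the median of -0.03 and the test's direction were opposite in sign to the mean of 0.08 (adjusted p = 0.608). GRHL2, an epithelial transcription factor, stood at -1.97 ± 0.12, ITGB4, an integrin of hemidesmosomes, at 1.78 ± 0.16, and DSP, the desmosomal plaque protein, at -1.46 ± 0.23, with DSP in the chromosome 6 stretch named above. In the interferon response list, 11 of 20 genes rose and 1 fell, also adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.00751, and adjusted p = 0.19 with an estimated correlation). With a filter of 1 CPM in 3 libraries its adjusted p was 0.0572 (range 0.000908 to 0.0572). MX1, an antiviral GTPase, stood at 2.75 ± 0.27 with 26 counts in wild-type cells (count ratio 6.84, 4.52 to 10.8), CMPK2, an interferon-induced kinase, at 2.27 ± 0.33, and IFI6, an interferon-induced mitochondrial protein, at 1.96 ± 0.37 and 1.24 without ORC2 deletion 2.

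In the hypoxia and glycolysis list, 9 of 22 genes rose and 1 fell, also adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0336, and adjusted p = 0.484 with an estimated correlation). The glucose transporter genes SLC2A3 and SLC2A1 stood at 4.22 ± 0.11 and 1.28 ± 0.12. That call was lost without wild-type 2 (adjusted p = 0.0579), wild-type 3 (0.0522) or ORC2 deletion 3 (0.0934) and with the GC and length offset (0.208), in a range of 0.0178 to 0.208. Of mitochondrially encoded transcripts, 8 of 13 rose, and 11 adjusted over the list alone, with a median of 0.6 (camera adjusted p = 0.00299, and adjusted p = 0.484 with an estimated correlation). The median was 0.34 without ORC2 deletion 2. CYTB, which encodes cytochrome b, stood at 1.05 ± 0.21 and at 0.72 without ORC2 deletion 2, and its call was lost in a fit of the compared groups alone (adjusted p = 0.0543, range 5.66e-10 to 0.0755). Of ribosomal protein genes, 2 of 81 rose, and 0 adjusted over the list alone in edgeR (5 at an unadjusted p below 0.05, 2 by DESeq2), with a median of 0.37 (camera adjusted p = 0.0336, and adjusted p = 0.857 with an estimated correlation). The ribosomal protein test turned to a lower direction without ORC2 deletion 2 (adjusted p = 0.019, median -0.12, 17 genes lower), and lost its call without wild-type 2 (0.0579) or 3 (0.0631) and with the GC and length offset (0.208), in a range of 0.000345 to 0.208.

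No other list passed the test in this comparison. Of HOX cluster genes, 10 of 30 rose and 4 fell, 11 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 0.0607), and the list passed without ORC2 deletion 2 (0.0421, and adjusted p = 0.427 with an estimated correlation) and with the filter of 1 CPM (0.0321), in a range of 0.0321 to 0.251. HOXB5 stood at 2.64 ± 0.28, HOXC6 at 1.62 ± 0.1 and HOXD4 at -1.93 ± 0.3. NRF2 targets had 1 of 17 higher and 2 lower (median -0.16, camera adjusted p = 0.309), and passed without ORC2 deletion 2 (0.019, and adjusted p = 0.271 with an estimated correlation) and with the GC and length offset (0.0452), in a range of 0.00849 to 0.615. GCLC, an enzyme of glutathione synthesis, stood at -1.13 ± 0.18. Of WNT targets, 4 of 13 rose and 3 fell, and the median of 0.08 differed in sign from the mean of -0.19 and the test (adjusted p = 0.976). SP5, a transcription factor, stood at 2.32 ± 0.24. Of 12 imprinted genes 1 rose and 1 fell (median -0.17, adjusted p = 0.127), the latter PEG10, a retrotransposon-derived gene, at -2.42 ± 0.27. Of the integrated stress response list, 8 of 21 rose and 2 fell (median 0.19, adjusted p = 0.26), with the transcription factor ATF3 at 1.15 ± 0.12.

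Of 393 zinc finger ZNF genes, 51 rose and 28 fell, 44 and 26 adjusted over the list alone (median 0, mean 0.07, test direction lower, adjusted p = 0.834), with ZNF461 at 3.49 ± 0.48 from 18 counts in wild-type cells (count ratio 11.1, 6.83 to 19.1). In the mitosis list 5 of 22 genes rose (median 0.02, adjusted p = 0.747). In the p53 target list 1 of 21 rose and 3 fell (median -0.16, adjusted p = 0.292). The NF-kB and inflammatory list had 4 of 13 higher and 1 lower (median 0.1, adjusted p = 0.299). Developmental transcription factors had 2 of 33 higher and 4 lower (median -0.01, adjusted p = 0.586). The cholesterol synthesis list had 2 of 23 higher and 1 lower (median 0.03, mean 0.07, test direction lower, adjusted p = 0.887). In the intestinal epithelium list 2 of 7 rose (median 0.48, adjusted p = 0.127), and of replication-dependent histones 3 of 31 rose (median 0.2, adjusted p = 0.887). Adjusted over the list alone, the numbers higher and lower were 5 and 0 for mitosis, 1 and 0 for p53 targets, 4 and 1 for NF-kB, 2 and 4 for developmental factors, 2 and 1 for cholesterol synthesis, 2 and 1 for intestinal epithelium and 0 and 0 for histones (5 and 1 at an unadjusted p below 0.05, 4 and 0 by DESeq2). They were 4 and 4 for WNT targets, 10 and 4 for the stress response, 0 and 1 for imprinted genes and 1 and 2 for NRF2 targets. Of 4 cancer-testis and germline genes, edgeR called 0 (0 at an unadjusted p below 0.05, 0 by DESeq2), and 0 of the 54 clustered protocadherins had enough counts to be tested. Among markers of other cell types stood COL1A1, a fibroblast collagen, at 1.35 ± 0.16 (1 of 4 higher, 1 lower), CD68 of macrophages at 0.67 ± 0.15 (2 of 7 blood cell markers higher, adjusted p = 0.26), VWF of endothelium at 2.91 ± 0.23 (2 of 3 higher) and SYT1 of neurons at -1.97 ± 0.15 (2 of 6 higher, 1 lower, adjusted p = 0.331). Of the lists that did not pass, the histone median turned to -0.47 in the fit without ORC2 deletion 2, with 2 genes higher and 2 lower, the blood cell marker median to -0.28, the fibroblast marker median from -0.19 to 0.58 and the epithelial adhesion median to 0.11. In that fit the medians were 0.03 for the stress response (8 higher and 5 lower), 0.28 for WNT targets (7 and 4), 0.23 for NF-kB (6 and 1), -0.08 for imprinted genes (2 and 2), 0.91 for endothelial and 0.24 for neural markers. The numbers higher and lower in it were 94 and 49 for ZNF genes, 7 and 5 for developmental factors, 7 and 5 for cholesterol synthesis, 3 and 6 for p53 targets and 8 and 0 for mitosis.

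ORC2 rescue against ORC2 deletion asks which of these genes change when ORC2 is expressed again. ORC2 was 15.1-fold higher in the rescue (log2 fold change 3.91 ± 0.14, adjusted p = 5.53e-08) and lay 8.04-fold above wild-type. By camera, the mesenchymal list was lower (8 of 15 genes called lower) and the origin licensing list higher (3 of 17 called higher) than in the deletion. Both list calls were lost with an estimated correlation (adjusted p = 0.094 and 0.177). PDE4B rose 40.4-fold to 36.1 ± 2.3 CPM, and ALPK2 fell 22.3-fold to 1.3 ± 0.302 CPM. By edgeR, 1003 genes were higher and 1424 lower, of which 331 and 782 changed at least 2-fold. They were 2839 and 3104 without ORC2 deletion 2, with 504 at least 2-fold higher. Without rescue 1 they were 575 and 905, and without rescue 3 they were 626 and 932. Of the 2427 genes, 2389 were also called in the same direction without ORC2 deletion 2, 2417 by DESeq2 and 701 in a fit of the compared groups alone, which called 231 higher and 473 lower (181 and 406 at least 2-fold).

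Among the largest increases at a mean CPM of at least 5 in either group, FSTL5, a secreted follistatin-like protein, rose by 4.54 ± 0.28 on the log2 scale, ZCCHC12, a zinc finger transcriptional coactivator, by 3.95 ± 0.11, and PCDH7 by 3.54 ± 0.16. DHRS2, a short-chain dehydrogenase, rose to 243 ± 36 from 22.2 ± 6.01 CPM, BDNF, a neurotrophin, to 127 ± 0.687 from 13.9 ± 3.06 CPM, and ANGPT2, an angiopoietin, to 14.4 ± 1.32 from 1.59 ± 0.101 CPM. In wild-type cells DHRS2, BDNF and ANGPT2 stood at 8.594 to 9.179, 33.16 to 34.89 and 3.702 to 4.695 CPM, below the rescue. Among the largest decreases at that level, WDR72, a WD repeat protein, had 4 counts in the rescue, a ratio of 405 (95% counting interval 158 to 1490), and PRSS33, a serine protease, had 8 counts, a ratio of 153 (77.6 to 357). WDR72 stood at 5.923 to 9.65 CPM in the deletion and 7.497 to 9.09 CPM in wild-type cells, so its fall was not a return. KRT13, a keratin of stratified epithelium, stood at -5.36 ± 0.48. The adjusted p of these genes ranged from 3.69e-09 (ZCCHC12) to 3.21e-05 (KRT13).

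Of 2747 genes higher in the ORC2 deletion, 874 (31.8%) were lower again in the rescue, and of 1834 genes lower in the deletion, 395 (21.5%) were higher again. Independent sets of these sizes would share 207.6 and 97.6 genes. In 20 simulations of unchanged groups with the same shared libraries it was 0, but those hold no changed genes, so neither value gives the overlap that the shared deletion libraries add among changed genes. Of the genes that moved back, 661 and 302 were not called different from wild-type in the rescue. In the rescue against wild-type, 1055 (38.4%) of the higher and 845 (46.1%) of the lower genes were still called in the deletion's direction, and 85 and 66 moved further. The covariance of the log2 fold changes of both comparisons was -0.39, against a mean of -0.072 in the simulations, and the correlation was -0.511, against -0.507. Leaving out ORC2 deletion 2, 1612 of 3706 (43.5%) and 1062 of 3212 (33.1%) moved back, and 2145 (57.9%) and 2036 (63.4%) were still called in the deletion's direction. Without rescue 1 the total of 1269 was 818. Among genes that moved back, ALPP stood at -6 ± 0.29, RARB at -5.98 ± 0.58 (count ratio 69.1, 45 to 112), AK5 at -5.47 ± 0.58, and PMEPA1, an inhibitor of TGF-beta signalling, at -4.91 ± 0.23 in the rescue against the deletion. EHF, an epithelial transcription factor, fell by 4.38 ± 0.38 after a rise of 6.4 ± 0.44 in the deletion, and EGF, a growth factor, by 4.08 ± 0.46 after 4.05 ± 0.47. EDN1, endothelin 1, fell by 3.95 ± 0.29 after a rise of 4.54 ± 0.31, although it lies in the chromosome 6 stretch that was lower in this clone. PRSS23, a serine protease, fell by 3.96 ± 0.18 and stood at 6.88 ± 0.436 CPM, against 6.92 ± 0.595 CPM in wild-type cells.

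**Figure D3:**
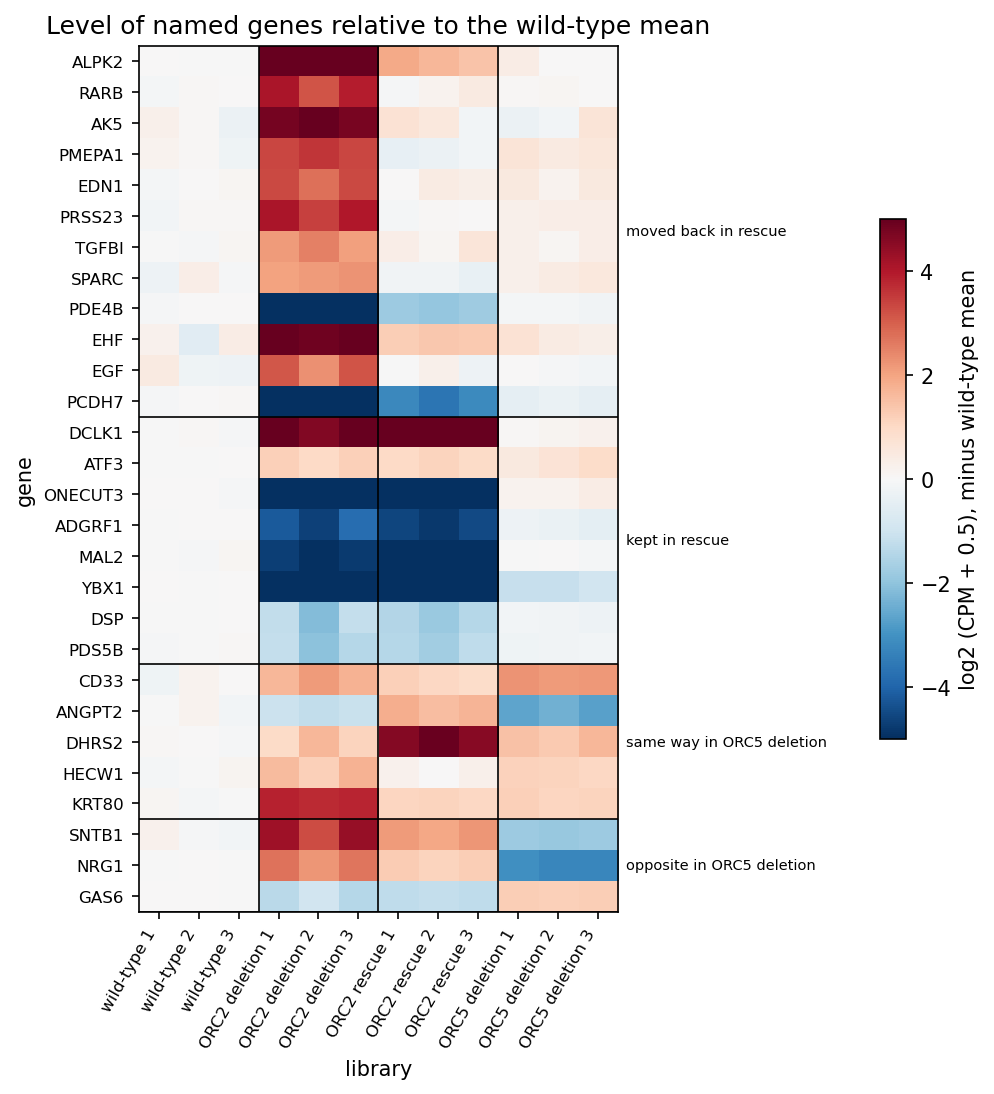
Level of named genes in each library as log2 difference from the wild-type mean, with colours saturating at 5 in either direction. YBX1 has a mean of 22 CPM in the ORC2 deletion, 26.2 CPM in the rescue and 572 CPM in the ORC5 deletion.

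In the mesenchymal and EMT list, 8 of 15 genes fell and 2 rose in the rescue, 10 and 3 adjusted over the list alone, with a median of -1.04 (camera adjusted p = 6.95e-05, and adjusted p = 0.094 with an estimated correlation). SPARC stood at -4.76 ± 0.48 (count ratio 27.5, 17.4 to 46.1), TGFBI at -3.45 ± 0.47 and VIM, vimentin, at -2.42 ± 0.14. In the origin licensing list, 3 of 17 rose, also adjusted over the list alone (median 0.19, camera adjusted p = 0.00686, and adjusted p = 0.177 with an estimated correlation). Without ORC2 the other 16 gave a single p = 0.00851 (p = 0.0475 with an estimated correlation). In the mitosis list, 5 of 22 genes fell, and 6 adjusted over the list alone (median -0.29, camera adjusted p = 0.00774, and adjusted p = 0.177 with an estimated correlation). In the epithelial adhesion list, 8 of 22 fell and 2 rose, 10 and 2 adjusted over the list alone (median -0.37, camera adjusted p = 0.0256, and adjusted p = 0.175 with an estimated correlation). ITGB4 stood at -2.3 ± 0.17 and KRT8, a keratin of simple epithelium, at -1.7 ± 0.2. That call was lost without rescue 3 (adjusted p = 0.0547, range 0.0105 to 0.0547). In the hypoxia and glycolysis list, 5 of 22 fell, and 7 adjusted over the list alone (median -0.23, camera adjusted p = 0.0169, and adjusted p = 0.413 with an estimated correlation). SLC2A3 stood at -1.78 ± 0.1 and LDHA, lactate dehydrogenase, at -0.59 ± 0.09, with LDHA's call lost in a fit of the compared groups alone (adjusted p = 0.0686, range 2.43e-14 to 1). The hypoxia call was lost without rescue 3 (0.082) and with the GC and length offset (0.0508), in a range of 0.00686 to 0.082, and its median was -0.13 without ORC2 deletion 2, with 8 genes lower. In that fit 9 licensing genes were higher and 1 lower, and 16 mitosis genes were lower, with the mitosis list also called with an estimated correlation (adjusted p = 0.0428).

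In the interferon response list, 4 of 20 fell in the rescue, also adjusted over the list alone (median -0.43, camera adjusted p = 0.0256, and adjusted p = 0.177 with an estimated correlation). IFIT1, an antiviral RNA-binding protein, stood at -1.73 ± 0.17. MX1 and CMPK2, named above as higher in the deletion, did not return to wild-type levels (0.1274 to 0.2058 and 0.1638 to 0.281 CPM). They stood at 0.7279 to 1.079 and 0.834 to 1.158 CPM in the rescue, against 0.946 to 1.204 and 0.7978 to 1.277 in the deletion. IFI6 stood at 12.26 to 17.69 CPM in the rescue, against 15.44, 46.76 and 16.13 in the deletion and 6.181 to 6.956 in wild-type cells. The interferon list's call was lost without ORC2 deletion 3 (adjusted p = 0.0661) and with the filter of 1 CPM (0.18), in a range of 0.0158 to 0.18, and 9 of 21 fell and 1 rose without ORC2 deletion 2. In the DNA repair list, 4 of 25 rose, and 7 adjusted over the list alone (median 0.35, camera adjusted p = 0.0012, and adjusted p = 0.58 with an estimated correlation), and the call was lost without ORC2 deletion 2 (0.0837, median 0.12, 8 genes higher, range 0.000134 to 0.0837). In the origin firing list, 2 of 36 rose, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0256, and adjusted p = 0.413 with an estimated correlation), and the call was lost without ORC2 deletion 2 (0.0922, 10 genes higher and 4 lower, range 0.0238 to 0.0922). RFC5 and PRIM1 stayed low, at 63.42 to 68.45 and 35.12 to 37.14 CPM in the rescue, against 114.4 to 115.5 and 55.85 to 57.17 in wild-type cells. In the intestinal epithelium list, 3 of 7 fell, also adjusted over the list alone (median -0.45, camera adjusted p = 0.0169, and adjusted p = 0.175 with an estimated correlation), with CA2, carbonic anhydrase 2, at -2.9 ± 0.24. That call was lost without ORC2 deletion 2 (0.088) and with the GC and length offset (0.0508), in a range of 0.0108 to 0.0882. The ribosomal protein list had a median of -0.34 (camera adjusted p = 0.0303, and adjusted p = 0.82 with an estimated correlation) with 0 of 81 genes called by edgeR, also adjusted over the list alone (1 higher and 3 lower at an unadjusted p below 0.05, 1 and 2 by DESeq2). It turned to a higher direction without ORC2 deletion 2 (0.000918, median 0.16) and lost its call without rescue 1 (0.183) or rescue 3 (0.203) and with the GC and length offset (0.16), in a range of 9.95e-05 to 0.203. The integrated stress response list, with 2 of 21 higher (median 0.04, camera adjusted p = 0.282), passed without ORC2 deletion 2 (0.0477, median 0.25, 11 higher and 1 lower, and adjusted p = 0.57 with an estimated correlation). The Polycomb (0.0315 and 0.0366), cohesin (0.0309 and 0.04) and blood cell marker lists (0.0491 and 0.0335) passed without ORC2 deletion 1 or 3, and in the fit of all libraries they had camera adjusted p = 0.0781, 0.165 and 0.0774 (adjusted p = 0.623, 0.751 and 0.554 with an estimated correlation). Without ORC2 deletion 2 these values were 0.586, 0.525 and 0.525 by camera, with medians of 0, -0.11 and -0.31, and the cohesin direction turned to lower. Outside the lists that passed, CBX2, a Polycomb subunit, stood at 1.15 ± 0.09, HOXB6 at -1.37 ± 0.11, HOXD4 at 2.81 ± 0.3, RNF43 at 2.86 ± 0.19 and MYC, a growth-promoting transcription factor, at 0.89 ± 0.15, with MYC's call lost in a fit of the compared groups alone (adjusted p = 0.0731, range 4.37e-11 to 0.16).

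ORC2 rescue against wild-type asks how far the rescue line lay from the parental cells. By camera, the epithelial adhesion and NRF2 target lists were lower and mitochondrially encoded transcripts higher in the rescue, with 9 of 22, 7 of 17 and 4 of 13 genes called that way. These 3 calls were lost with an estimated correlation (adjusted p = 0.0723, 0.127 and 0.409). ORC2 stood at 589 ± 59.4 CPM against 73.3 ± 1.29 CPM. DCLK1 rose further than in the deletion, to 55.9 ± 6.21 CPM, with 8 counts in wild-type cells (ratio 1150, 95% counting interval 584 to 2670). YBX1 stood at 26.2 ± 1.78 CPM, near its level in the deletion. By edgeR, 1863 genes were higher and 1557 lower, of which 884 and 654 changed at least 2-fold. They were 4372 and 4240 without ORC2 deletion 2. Without wild-type 1, 2 or 3 the higher counts were 1209, 1189 and 1164, and without wild-type 2, wild-type 3 or rescue 1 the lower counts were 1014, 1006 and 1018. Of the 3420 genes, 3419 were also called in the same direction without ORC2 deletion 2, 3400 by DESeq2 and 3310 in a fit of the compared groups alone, which called 3825 higher and 3522 lower.

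FSTL5 rose by 8.6 ± 0.4 on the log2 scale from 4 counts in wild-type cells (count ratio 425, 166 to 1560), DHRS2 by 4.77 ± 0.21, ZCCHC12 by 4.35 ± 0.11 and MKX, a homeobox transcription factor, by 3.56 ± 0.31. WDR72 fell by 8.58 ± 0.43 to 4 counts (count ratio 422, 164 to 1550), ONECUT3 by 7.86 ± 0.3, ADGRF1 by 6.84 ± 0.42 to 27 counts (116, 79.3 to 176), MAL2 by 5.82 ± 0.18 and YBX1 by 5.55 ± 0.11. The adjusted p of these genes ranged from 3.16e-10 (YBX1) to 1.88e-05 (MKX). In the epithelial adhesion list, 9 of 22 genes fell, and 12 fell and 1 rose adjusted over the list alone (median -0.43, camera adjusted p = 0.00148, and adjusted p = 0.0723 with an estimated correlation). ITGA6, an integrin, stood at -1.64 ± 0.3, CLDN4, a tight junction claudin, at -1.1 ± 0.12, and DSP, in the chromosome 6 stretch, at -1.57 ± 0.23. Of NRF2 targets, 7 of 17 fell and 1 rose, 9 and 1 adjusted over the list alone (median -0.5, camera adjusted p = 0.00868, and adjusted p = 0.127 with an estimated correlation), with GCLC at -0.86 ± 0.18 and FTH1, ferritin heavy chain, at -0.91 ± 0.19. Of mitochondrially encoded transcripts, 4 of 13 rose, and 8 adjusted over the list alone (median 0.51, camera adjusted p = 0.00148, and adjusted p = 0.409 with an estimated correlation), with ND1, a subunit of complex I, at 0.68 ± 0.15. In the cohesin, condensin and CTCF list, 1 of 19 fell, also adjusted over the list alone (median -0.33, camera adjusted p = 0.0227, and adjusted p = 0.997 with an estimated correlation), which was PDS5B at -1.48 ± 0.2. In the integrated stress response list, 5 of 21 rose, and 9 rose and 2 fell adjusted over the list alone (median 0.27, camera adjusted p = 0.0261, and adjusted p = 0.409 with an estimated correlation), with ATF5 at 1.22 ± 0.2 and ATF3 at 1.05 ± 0.12. Without rescue 2, the cohesin and stress response calls were lost (both adjusted p = 0.0691, in ranges of 0.000458 to 0.0691 and 0.0125 to 0.0691), leaving 3 lists called. Without ORC2 deletion 2, origin firing (0.0167, range 0.0167 to 0.107) and mitosis (0.0058, range 0.00101 to 0.107) also passed, with lower directions, and both were lost with an estimated correlation (adjusted p = 0.527 and 0.131). In that fit 15 epithelial adhesion genes were lower and 3 higher, 11 NRF2 targets lower and 1 higher, 13 mitochondrial transcripts higher, 15 cohesin genes lower, and 13 stress response genes higher and 4 lower. The mesenchymal and EMT list still had 6 of 15 genes higher than wild-type and 1 lower (camera adjusted p = 0.0946, range 0.0362 to 0.262). It passed without both replicate 2 libraries (0.0362). Without ORC2 deletion 2 it had 8 higher and 1 lower (median 0.48, adjusted p = 0.0541, and 0.253 with an estimated correlation). Outside the lists that passed, CCN2 stood at 2.33 ± 0.16, CCN1, a related matrix-associated protein, at 2.04 ± 0.15, HOXC6 at 1.17 ± 0.1, and JARID2, a Polycomb cofactor in the chromosome 6 stretch, at -1.59 ± 0.17. GMNN in the same stretch stood at -0.98 ± 0.09, and COL3A1, a fibroblast collagen, at 5.5 ± 0.7 from 6 counts in wild-type cells (count ratio 46.8, 21.3 to 128).

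Runs of neighbouring genes were shifted together, taken as windows with a median log2 fold change of at least 0.5 in size. In windows of chromosome 6 from 1 to 10000000, 10000001 to 20000000 and 20000001 to 30000000, the median log2 fold changes against wild-type were -0.92, -0.85 and -0.78 in the ORC2 deletion and -1, -1.03 and -1.14 in the rescue. On chromosome 13 from 110000001 to 120000000 they were -0.65 and -0.84, and on chromosome 18 from 30000001 to 40000000 they were -0.93 and -0.94. Windows past that limit in the rescue but not in the deletion lay on chromosome 17 from 80000001 (0.86, and 0.33 in the deletion), chromosome X from 130000001 (0.87 and -0.14) and from 150000001 (1.07 and 0.33), and chromosome 2 from 220000001 (-0.56 and -0.34). Their medians in the rescue against the deletion were 0.45, 1.07, 0.68 and -0.17, and the differences of windows were not tested. In the ORC5 deletion 1 window passed the limit, on chromosome 10 from 1 to 10000000 (-0.51, with 20 of 20 genes at negative values and 4 called lower). Genes in these windows were 2.9% of calls in the ORC2 deletion, 8.4% in the rescue and 2.6% in the ORC5 deletion, each against wild-type. The windows held 265, 511 and 46 of the 18846 genes tested, a smaller share than that of the calls. They were chosen by their shift, so part of that excess follows from the choice.

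**Figure D4:**
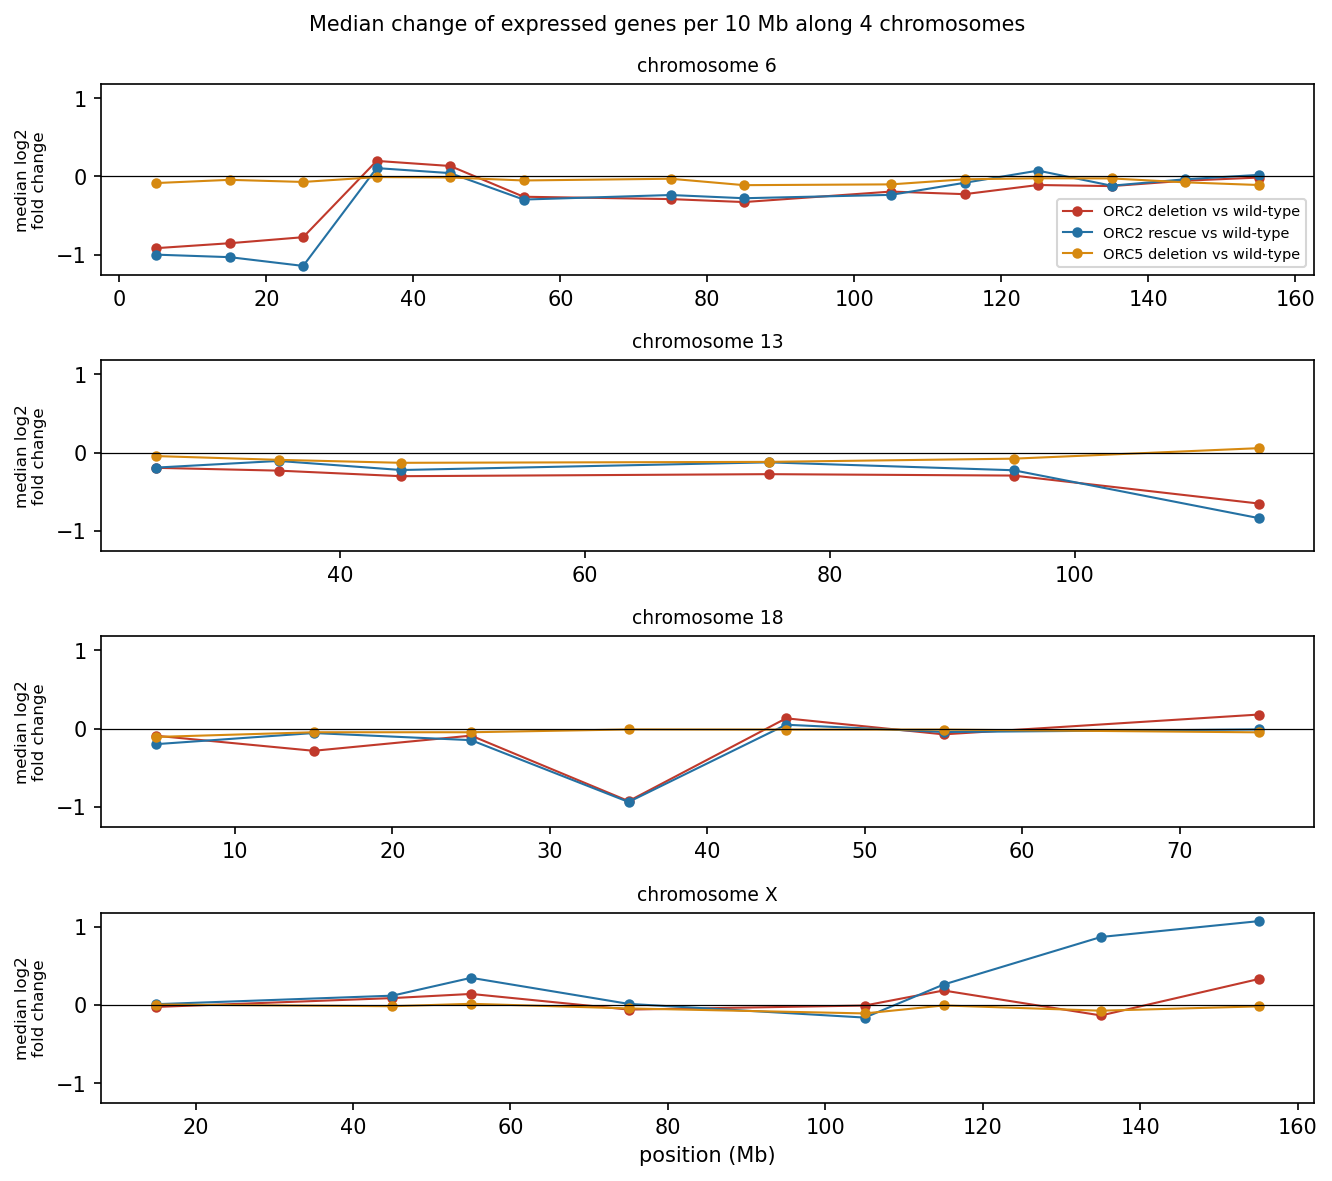
Median log2 fold change against wild-type in windows of 10 Mb along 4 chromosomes, for each comparison with wild-type. Windows of chromosome 6 up to 30000000 lie at -0.92 to -0.78 in the ORC2 deletion and at -1.14 to -1 in the rescue.

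ORC5 deletion against wild-type asks what differs in a clone in which the gene of another subunit of the complex was targeted. By camera, the hypoxia and interferon lists were higher (1 of 22 and 1 of 20 genes called higher) and the cholesterol synthesis list lower (1 of 23 called lower). These 3 calls were lost with an estimated correlation (adjusted p = 0.0763 each). CD33, a sialic acid binding receptor, was 6.4-fold higher at 5.83 ± 0.285 against 0.907 ± 0.186 CPM, and MTHFD2L, a mitochondrial folate enzyme, 6.34-fold higher at 106 ± 4.57 against 16.8 ± 0.737 CPM. ORC5 stood at 35.4 ± 0.63 against 47.4 ± 2.45 CPM (log2 fold change -0.42 ± 0.1, adjusted p = 0.0953), and its adjusted p was 0.000395 without ORC2 deletion 2, in a range of 1.44e-06 to 1. ORC2 stood at -0.03 ± 0.13 (adjusted p = 0.987). By edgeR, 107 genes were higher and 45 lower, of which 67 and 25 changed at least 2-fold. Without ORC2 deletion 2, which is in neither group, the counts were 1196 and 899, with 255 and 48 at least 2-fold. With the replicate number as a block, 66 were higher. Counts were 37 to 61 higher and 20 to 29 lower without 1 of wild-type 1 to 3, rescue 1 or ORC5 deletion 1 to 3. At least 2-fold higher were 27 to 43 genes without 1 of these libraries, and 16 were at least 2-fold lower without ORC5 deletion 2. Each of the 152 genes was also called in the same direction without ORC2 deletion 2 and by DESeq2, and 149 were in a fit of the compared groups alone, which called 2136 higher and 2123 lower (304 and 60 at least 2-fold).

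SULT1A1, a sulfotransferase, stood at 1.64 ± 0.19, DHRS2 at 1.53 ± 0.19 and HECW1, a ubiquitin ligase, at 1.28 ± 0.17. WDR72 stood at -3.87 ± 0.29, AMOTL1, an angiomotin family protein, at -2.31 ± 0.21, FAM124A at -1.26 ± 0.12 and YBX1 at -1.1 ± 0.1 (572 ± 45 CPM). ZNF354A, a zinc finger gene, stood at -1.53 ± 0.15, HNRNPAB, an RNA-binding protein, at -1.25 ± 0.09 and RMND5B, a ubiquitin ligase subunit, at -1.05 ± 0.16 (adjusted p = 0.0106), all on chromosome 5. The call of RMND5B was lost without wild-type 1, 2 or 3 (adjusted p = 0.0505, 0.0577 and 0.0556) and without ORC5 deletion 2 (0.0794) or 3 (0.0539), in a range of 2.56e-11 to 0.313.

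In the hypoxia and glycolysis list, 1 of 22 genes rose, and 10 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 4.78e-08, and adjusted p = 0.0763 with an estimated correlation). In the interferon response list, 1 of 20 rose, and 4 adjusted over the list alone (median 0.3, camera adjusted p = 0.00257, and adjusted p = 0.0763 with an estimated correlation). In the origin licensing list edgeR called 0 of 17 (3 lower at an unadjusted p below 0.05, 3 by DESeq2), and 1 lower adjusted over the list alone, with a median of -0.2 (camera adjusted p = 0.000224, and adjusted p = 0.0763 with an estimated correlation). With the targeted ORC5 taken out, its other 16 genes gave a single unadjusted camera p = 0.000203 (p = 0.00865 with an estimated correlation), a test added after the data were seen. MCM2 stood at -0.26 ± 0.23 (adjusted p = 0.843), MCM5 at -0.34 ± 0.19 (0.629) and MCM7 at -0.26 ± 0.19 (0.777), and without ORC2 deletion 2 their adjusted p were 0.0101, 0.003 and 0.00925, in ranges of 3.11e-05 to 1, 4.04e-07 to 1 and 6.46e-06 to 1. In the origin firing list edgeR called 0 of 36, also adjusted over the list alone (2 lower at an unadjusted p below 0.05, 2 by DESeq2), with a median of -0.14 (camera adjusted p = 0.000135, and adjusted p = 0.095 with an estimated correlation). In the mitosis list it called 0 of 22, also adjusted over the list alone (2 lower unadjusted, 1 by DESeq2), with a median of -0.14 (camera adjusted p = 0.00372, and adjusted p = 0.143 with an estimated correlation). In the cohesin list it called 0 of 19, also adjusted over the list alone (1 lower unadjusted, 0 by DESeq2), with a median of -0.18 (camera adjusted p = 0.00531, and adjusted p = 0.617 with an estimated correlation). In the cholesterol synthesis list 1 of 23 fell, and 2 adjusted over the list alone (median -0.21, camera adjusted p = 0.000224, and adjusted p = 0.0763 with an estimated correlation).

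The mesenchymal and EMT list had a median of 0.4 in the ORC5 deletion (camera adjusted p = 0.00367, and adjusted p = 0.095 with an estimated correlation). Of its 15 genes edgeR called 0 (6 higher at an unadjusted p below 0.05, 1 by DESeq2), and 4 higher adjusted over the list alone. LOXL2, a lysyl oxidase, stood at 0.4 ± 0.12 (adjusted p = 0.176, and 0.000116 without ORC2 deletion 2, in a range of 3.03e-07 to 1). The DNA repair list had a median of -0.12 (camera adjusted p = 0.0179, and adjusted p = 0.663 with an estimated correlation), with 0 of 25 called, also adjusted over the list alone (1 lower unadjusted, 0 by DESeq2). Without ORC5 deletion 3 the mesenchymal and repair calls were lost (adjusted p = 0.0548 and 0.12), as with the GC and length offset (0.073 and 0.161), in ranges of 0.000593 to 0.073 and 0.00121 to 0.161. Without ORC2 deletion 2 the HOX (0.0369), WNT (0.0353), NRF2 (0.0156) and mitochondrial (0.0377) lists also passed, in ranges of 0.00646 to 0.35, 0.0319 to 0.333, 0.00181 to 0.107 and 0.0248 to 0.75. These 4 calls were lost with an estimated correlation (adjusted p = 0.265, 0.123, 0.138 and 0.578). With the replicate block the NRF2 list passed (0.0409). Of the lists called, the fit without ORC2 deletion 2 had 13 of 22 hypoxia genes higher and 1 lower, 7 of 21 interferon genes higher and 1 lower, 5 of 15 mesenchymal genes higher, 9 of 23 cholesterol synthesis genes lower and 1 higher, and 8 of 17 licensing, 10 of 36 firing, 4 of 22 mitosis, 6 of 19 cohesin and 1 of 25 repair genes lower. With an estimated correlation, the licensing, mitosis, mesenchymal and cholesterol synthesis lists passed in that fit (adjusted p = 0.0368 each). Of replication-dependent histones, 3 of 31 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0582, and adjusted p = 0.663 with an estimated correlation), with H2AC6 at 1.21 ± 0.17. That list passed without wild-type 1 (0.0323), wild-type 3 (0.0336) or ORC5 deletion 2 (0.0307), with RLE size factors (0.042) and with the filter of 1 CPM (5.28e-08), in a range of 5.28e-08 to 0.222.

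**Figure D5:**
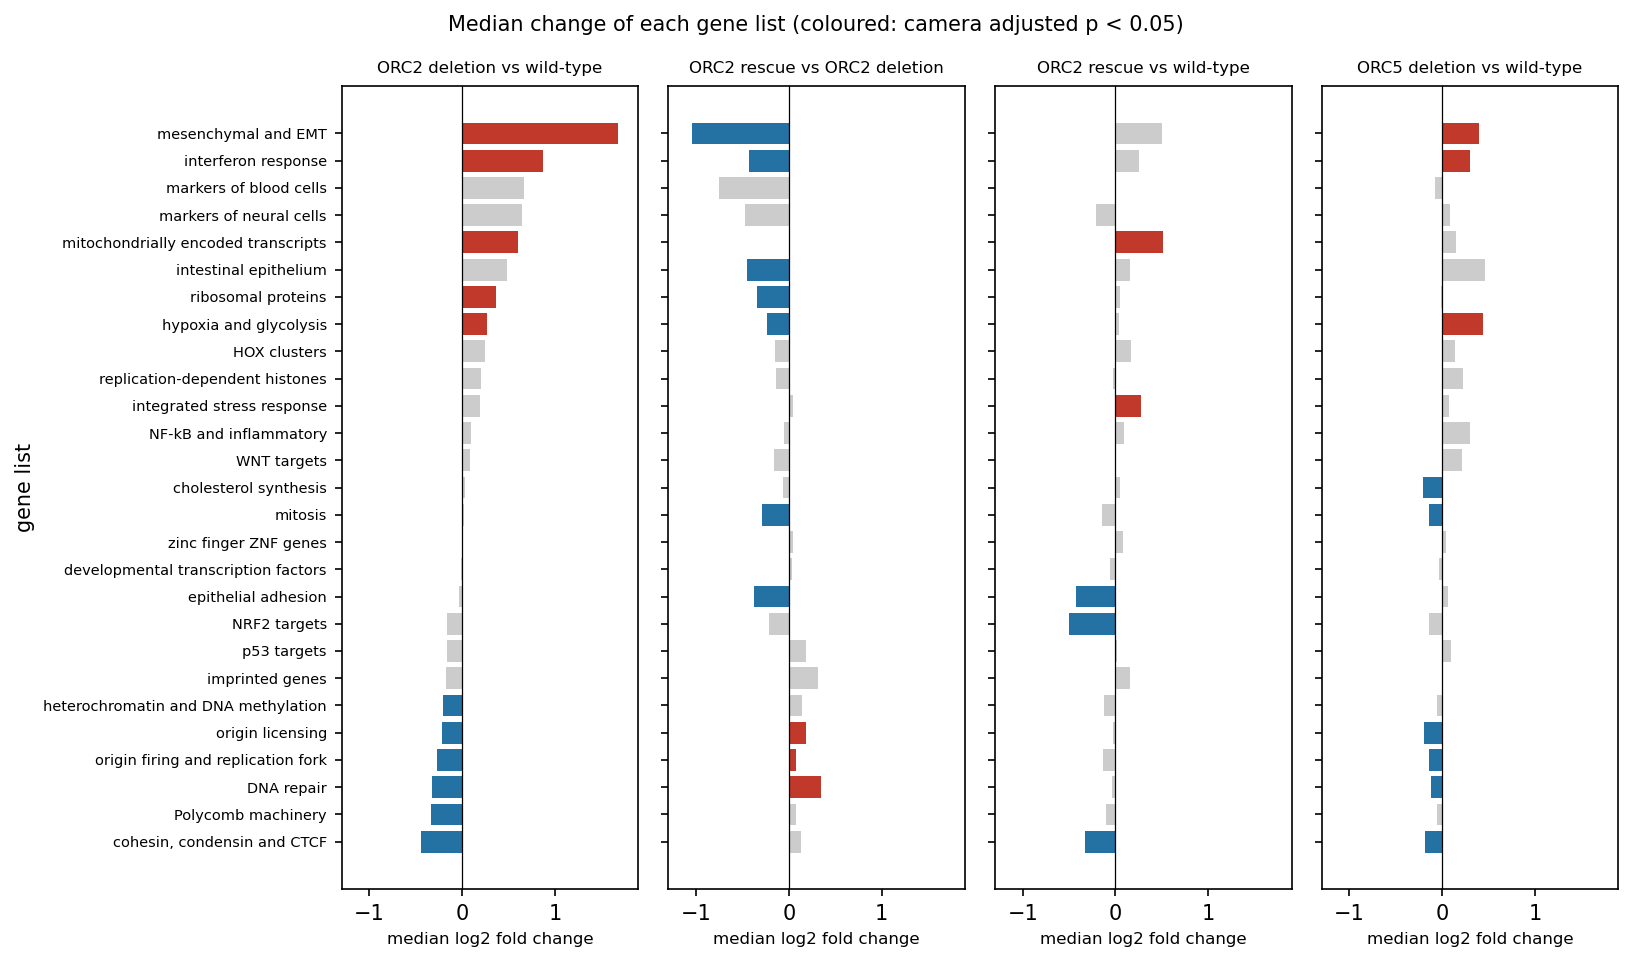
Median log2 fold change of the gene lists in 4 of the comparisons, coloured at a camera adjusted p below 0.05. The mesenchymal and EMT list stands at 1.68 in the ORC2 deletion, at -1.04 in the rescue against the deletion and at 0.4 in the ORC5 deletion.

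Changes shared by both deletions were counted against wild-type, which both comparisons use. Genes changed the same way numbered 70 higher and 19 lower, where independent sets would share 15.6 and 4.4. In 20 simulations of unchanged groups it was 0, which leaves out real changes as the former leaves out the shared wild-type libraries, so neither gives the overlap those libraries add among changed genes. Genes changed in opposite ways numbered 8 and 15, where independent sets would share 6.6 and 10.4. The covariance of the log2 fold changes was 0.184, against 0.071 in the simulations, and the correlation was 0.373, against 0.504. Without ORC2 deletion 2 the opposite genes numbered 251, below the 369.5 of independent sets, and the genes changed the same way were 621 higher and 423 lower, against 228.3 and 148.7. The 89 genes changed the same way were thus 1044 in that fit and 54 with the replicate block. They were 27 to 48 without 1 of wild-type 1 to 3, rescue 1 or ORC5 deletion 1 to 3. KRT80, a keratin of epithelium, rose in both (3.92 ± 0.11 in the ORC2 deletion, 1.21 ± 0.1 in the ORC5 deletion), as did CD33 (2.31 ± 0.19 and 2.68 ± 0.2), HECW1 (1.75 ± 0.17 and 1.28 ± 0.17) and DHRS2 (1.32 ± 0.18 and 1.53 ± 0.19). ANGPT2 fell in both (-1.38 ± 0.17 and -3.9 ± 0.21). Of the 19 lower genes, only ANGPT2 (1.79) and ZNF831 (0.7) had positive log2 changes in the rescue against wild-type. In opposite ways changed NRG1, a growth factor (2.68 ± 0.21 and -6.54 ± 0.33, with 9 counts in the ORC5 deletion, a count ratio of 96 from 50.3 to 211), SNTB1, a syntrophin (4.31 ± 0.27 and -3.08 ± 0.32), and GAS6, a ligand of receptor tyrosine kinases (-1.24 ± 0.12 and 1.23 ± 0.12). GAS6 lies in the window of chromosome 13 that was lower in the ORC2 deletion.

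ORC2 deletion against ORC5 deletion tests the difference between the deletions itself. By camera, the mesenchymal and EMT list was higher in the ORC2 deletion, with 10 of 15 genes called higher, and that call was lost with an estimated correlation (adjusted p = 0.193). ORC2 stood at -0.87 ± 0.13 (adjusted p = 0.000772, and 0.0855 by glmTreat). By edgeR, 2173 genes were higher and 1740 lower, of which 992 and 696 differed at least 2-fold. They were 3434 and 3174 without ORC2 deletion 2, and without ORC5 deletion 1, 2 or 3 they were 1230 and 1025, 1214 and 1017, and 1341 and 1133. Of the 3913 genes, 3779 were also called in the same direction without ORC2 deletion 2, 3898 by DESeq2 and 1294 in a fit of the compared groups alone, which called 739 higher and 562 lower (557 and 411 at least 2-fold). NRG1 was higher in the ORC2 deletion by a count ratio of 634 (95% counting interval 334 to 1390), ALPK2 by 7.73 ± 0.34, DCLK1 by 7.56 ± 0.31, SNTB1 by 7.38 ± 0.33 and ALPP by 7.37 ± 0.33 on the log2 scale (count ratios 216, 148 to 328, for ALPK2, 202, 129 to 336, for DCLK1 and 161, 109 to 250, for ALPP). ONECUT3 stood at -7.24 ± 0.29, PDE4B at -7.06 ± 0.3, PCDH7 at -6.52 ± 0.18 and RNF43 at -6.22 ± 0.21. The adjusted p of the genes from NRG1 to RNF43 ranged from 2.99e-09 (PCDH7) to 1e-07 (SNTB1).

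Of mesenchymal and EMT genes, 10 of 15 were higher in the ORC2 than in the ORC5 deletion and 2 lower, also adjusted over the list alone (median 1.44, camera adjusted p = 0.00102, and adjusted p = 0.193 with an estimated correlation), with CCN2 at 3.28 ± 0.16 and VIM at 2.94 ± 0.14. Of DNA repair genes, 5 of 25 were lower and 1 higher, 6 and 2 adjusted over the list alone (median -0.27, camera adjusted p = 0.0496, and adjusted p = 0.671 with an estimated correlation), with FANCA at -0.53 ± 0.09. FANCA's call was lost in a fit of the compared groups alone (adjusted p = 0.0558, range 2.55e-08 to 1). Of ribosomal protein genes, 4 of 81 were higher, and 0 adjusted over the list alone in edgeR (10 at an unadjusted p below 0.05, 7 by DESeq2; median 0.39, camera adjusted p = 0.0241, and adjusted p = 0.773 with an estimated correlation). Of mitochondrially encoded transcripts, 4 of 13 were higher, and 6 adjusted over the list alone (median 0.53, camera adjusted p = 0.026, and adjusted p = 0.617 with an estimated correlation). Without ORC5 deletion 1 or 2, the repair (adjusted p = 0.0865 and 0.0797), ribosomal (0.0844 and 0.0514) and mitochondrial (0.0844 and 0.0797) calls were lost, leaving 1 list called. Without ORC2 deletion 2, the repair list gave 0.391 (median -0.06), the ribosomal list turned to a lower direction (0.0675, median -0.11, 15 genes lower and 5 higher) and the mitochondrial median was 0.25, with 8 genes higher. In that fit the mitosis list passed as higher (0.00238, 11 of 22 genes higher) and the cholesterol synthesis list as higher (0.0232, 10 of 23 higher and 2 lower), and both were lost with an estimated correlation (adjusted p = 0.096 and 0.292). Imprinted genes, with 3 of 12 lower (median -0.31, camera adjusted p = 0.101, and adjusted p = 0.645 with an estimated correlation), passed in 9 of 12 fits that left out 1 library (0.0191 to 0.0479). Without ORC2 deletion 2 they did not pass (adjusted p = 0.244, median -0.19, 1 of 13 higher and 4 lower). The cohesin list, with 1 of 19 lower (median -0.29, camera adjusted p = 0.0735, and adjusted p = 0.671 with an estimated correlation), passed without ORC2 deletion 1 (0.0141) or 3 (0.0191). Without ORC2 deletion 2 the cohesin median was -0.09 (adjusted p = 0.459), with 2 genes higher and 5 lower. With the GC and length offset the repair list gave 0.261 and the ribosomal list 0.0631, and with RLE size factors the repair list gave 0.0559. Over the alternatives, the adjusted p ranged from 0.0121 to 0.391 for repair, from 2.59e-05 to 0.0844 for ribosomal proteins and from 0.00567 to 0.0844 for mitochondrial transcripts. Outside the lists that passed, GRHL2 stood at -2.04 ± 0.12, MX1 at 2.17 ± 0.26 and GAS6 at -2.47 ± 0.12.

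Of the 830 genes on the authors' deposited list of genes higher after ORC2 deletion, 758 were tested and 744 (98.2%) were called higher by edgeR, and 428 were lower again in the rescue. Of the 235 genes on the authors' deposited list of lower genes, 233 were tested and 230 (98.7%) were called lower, and 108 were higher again in the rescue. In the rescue against the deletion, 757 of the 758 and 233 of the 233 had the opposite sign, against 70.068% of all genes tested. The lists may thus have been chosen with the rescue in view, so their counts of return do not test it. The authors' deposited lists were drawn from these libraries and are not independent evidence.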

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

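The tests of GC content and length for ORC2 deletion 2, and of return in the rescue for the runs of genes and for YBX1, were chosen after the result was seen. The difference between both deletions was itself tested by edgeR for genes and by camera for lists. ORC2 differed by -0.87 on the log2 scale (ORC2 deletion minus ORC5 deletion), in a direction that its targeting in 1 of the clones implies. Genes higher in the ORC2 deletion were NRG1 (9.22), ALPK2 (7.73), DCLK1 (7.56), SNTB1 (7.38), ALPP (7.37), CCN2 (3.28), VIM (2.94) and MX1 (2.17). Genes lower in it were ONECUT3 (-7.24), PDE4B (-7.06), PCDH7 (-6.52), RNF43 (-6.22), GAS6 (-2.47), GRHL2 (-2.04) and FANCA (-0.53). The lists that differed were DNA repair (median -0.27), mesenchymal and EMT (1.44), ribosomal proteins (0.39) and mitochondrially encoded transcripts (0.53), with ORC2 deletion 2 left out the ribosomal median turned to -0.11 and the repair and mitochondrial medians were -0.06 and 0.25, and none of the 4 passed with an estimated correlation (0 of 27, 2 at an unadjusted p below 0.05, against 11 by fry).

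ORC2 deletion 2 stood apart from replicates 1 and 3. After the trend with GC content and transcript length was removed, its median deviation was 0.439, against at most 0.176 in the other groups, so that trend is part but not the whole of the difference. Genes at least 8-fold higher in another group than in replicates 1 and 3 gave no sign of RNA from that group, with a median share of -6e-04 over 22 wild-type genes and of -0.0032 over 11 rescue genes. What stays open is a difference in RNA quality, library preparation or culture, for which the labels hold no value, and no biological explanation was tested.

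Runs of neighbouring genes were shifted together in 5 windows of the ORC2 deletion, 9 of the rescue and 1 of the ORC5 deletion. With an offset for GC content and length the median size of the shift was 0.82, which argues against such a bias as the whole cause. A copy number difference between clones may account for the shifts, since weakly expressed genes that had no part in the choice of windows moved in the same direction by a median of 0.76. That value rests on the rescue (0.8, from -0.24 to 1.24), and it was 0.21, from -0.14 to 0.9, in the windows of the ORC2 deletion and 0.19 in that of the ORC5 deletion, so copy number is less certain there. The shifts of the ORC2 deletion did not return when ORC2 was expressed again (median share undone -0.12), and DNA was not measured.

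YBX1 stood at 1220 CPM in wild-type cells, 22 in the ORC2 deletion, 26.2 in the rescue and 572 in the ORC5 deletion. Its reads had not moved to 10 pseudogenes, whose summed CPM went from 5.92 to 0.0898 (-0.0048 of the loss). A deletion of a wider stretch is argued against by a median of 0.2 over 18 expressed genes within 1 Mb. A dependence on ORC2 that its re-expression undoes is argued against by a regained share of 0.0035. A change of YBX1 alone in these clones, or a lasting change that began with the loss of ORC2, stays open as untested.

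The 6 libraries of each comparison can be split in 10 ways, which is too few for a share under 0.05. The real split called 4581 genes in the ORC2 deletion, 2427 in the rescue against the deletion, 3420 in the rescue against wild-type, 152 in the ORC5 deletion and 3913 between the deletions, and in each 1 of 10 splits, the real one, reached that count. The highest other split called 0 by edgeR in each. At an unadjusted p below 0.05 the highest other splits called 2126, 5680, 273, 225 and 2647 genes, against 7277, 4941, 5926, 1947 and 6634. In the rescue against the deletion another split thus exceeded the real one without adjustment, which points to a structure of those libraries besides their groups.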

How the results depend on the processing

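The fit without both replicate 2 libraries, the quality weights and the GC and length offset were chosen after the data were seen. No named gene that was called reversed under any alternative. ORC2 in the ORC5 deletion, not called, reversed to 0.06 with the GC and length offset; the cause was not tested. Counts below are higher and lower, in the order ORC2 deletion, rescue against deletion, rescue against wild-type, ORC5 deletion, and ORC2 against ORC5 deletion, with at least 2-fold counts in parentheses where they moved by over 1.5 times.

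With DESeq2 the ORC5 deletion gave 339 and 206 (154 and 40), and 298 genes changed the same way in both deletions. Without a filter on low counts 646 genes were higher in the rescue against the deletion. A fit of only the groups compared gave 990 and 534 (755 and 342), 231 and 473 (181 and 406), 3825 and 3522, 2136 and 2123 (304 and 60), and 739 and 562 (557 and 411). This fit has fewer libraries and its own spread, with ORC2 deletion 2 in the first, second and last. With the replicate number as a block 66 genes were higher in the ORC5 deletion and 54 changed the same way in both deletions. The block moved no other count by over 1.5 times and, of the list calls, changed only NRF2 targets in the ORC5 deletion. glmTreat against 1.5-fold, a stricter test by construction, gave 871 and 401, 209 and 523, 559 and 444, 22 and 16, and 627 and 437, with 343 genes moved back and 15 the same way. Without both replicate 2 libraries the counts were 4526 and 4283, 3294 and 3526, 4540 and 4395, 2204 and 2621 (383 and 75), and 4478 and 4083, with 3581 moved back and 2456 the same way. With quality weights they were 4770 and 4416, 4101 and 4433 (705 higher), 5607 and 5470 (1414 and 1026), 2307 and 2115 (462 and 100), and 4463 and 4300, with 4084 moved back and 2196 the same way. With the GC and length offset they were 2868 lower in the ORC2 deletion, 2088 and 2421, 3031 and 2725, 387 and 280 (121 higher), and 3362 and 2873, with 2340 moved back and 353 the same way. The cause of the differences by DESeq2, by the filter, by the block, by the weights and by the offset was not tested.

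With an estimated correlation 0 lists were called in each comparison (4, 6, 2, 8 and 2 at an unadjusted p below 0.05), and without ORC2 deletion 2 it called 1 list in the rescue against the deletion and 4 in the ORC5 deletion. By fry 11 were called in the rescue against wild-type and 11 between the deletions. With a preset correlation 1, 1 and 2 chromosomes were called in the ORC2 deletion, the rescue against the deletion and the rescue against wild-type, against 0 with an estimated one.

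Leaving out 1 library at a time, the counts ranged from 1677 to 3706 and 1085 to 3212 (1052 to 1850 and 487 to 755) in the ORC2 deletion, from 575 to 2839 and 905 to 3104 (259 to 504 and 591 to 874) in the rescue against the deletion, and from 1164 to 4372 and 1006 to 4240 (678 to 1155 and 528 to 878) in the rescue against wild-type. They ranged from 37 to 1196 and 20 to 899 (27 to 255 and 16 to 48) in the ORC5 deletion and from 1214 to 3434 and 1017 to 3174 (706 to 1361 and 532 to 833) between the deletions. Genes moved back ranged from 818 to 2674 and genes changed the same way from 27 to 1044. Lists called ranged from 8 to 11, 7 to 15, 3 to 7, 8 to 13 and 1 to 6, and the authors' deposited genes called from 577 to 756 and 199 to 232. Of 158 calls of named genes, each was kept with RLE size factors, DESeq2 and limma-voom, 151 in a fit of the compared groups alone and 138 by glmTreat, which did not call ORC2 in the ORC2 deletion (adjusted p = 0.0516). With few counts in a group, depth limits the ratios given with intervals.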

Other observations

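The tests below were made on genes noticed in these data, and their lists were written after the first results were seen.

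ANKRD1, CCN1 and CCN2, all known targets of the transcriptional coactivator YAP, were higher in the ORC2 deletion. Other targets of YAP were therefore examined, leaving out these genes and CCDC80. Of 18 listed genes 15 were tested, of which 8 rose and 1 fell in the ORC2 deletion against wild-type, with a median log2 fold change of 0.53 (single camera p = 0.00328, and p = 0.326 with an estimated correlation). The median was 0.78 without ORC2 deletion 2. In the rescue against the deletion 5 fell and 1 rose, with a median of -0.18 (p = 0.0213, and p = 0.436 with an estimated correlation), and of -0.52 without ORC2 deletion 2. In the rescue against wild-type 6 of the 15 were higher and 1 lower, with a median of 0.29 (p = 0.0273, and p = 0.455 with an estimated correlation). For the ORC5 deletion against wild-type the median of the same genes was 0.17. Higher YAP activity in the ORC2 deletion may account for the median of 0.53, as a hypothesis found and tested on the same data.

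HNRNPAB, ZNF354A and RMND5B, which were among the 8 largest called decreases of the ORC5 deletion at a mean CPM of at least 5 in either group, lie close together on chromosome 5. The other 3 expressed genes between them (178131014 to 178730659) had a median log2 fold change of -0.78 in the ORC5 deletion (-0.97 to -0.7). A loss of that segment in the ORC5 deletion clone may account for these decreases (median -0.78), and DNA was not measured.

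By chromosome, 0 chromosomes passed camera with an estimated correlation in each of the 5 comparisons, with 1 at an unadjusted p below 0.05 in the rescue against the deletion and 1 in the rescue against wild-type.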
